A study of Homo sapiens with 9 samples.

How the data were processed

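The values analysed are RPKM (reads scaled to the length of the gene and the size of the library) that the authors deposited in 1 table of 58037 genes and 9 columns, all of which were used (0 unused columns). The submitters' processing notes name STAR, HTSeq and the genome build GRCh38. The versions, the gene annotation and the strand setting of the counting are not given in the sources used here, so values of genes that overlap another gene on the opposite strand, and of pseudogenes, are uncertain. Multiplied by the exon length of each gene in GENCODE release 29, the low values of every library were whole multiples of a single step (100% whole within 0.05 of a read), as RPKM from whole read counts are. 92.5% of the gene identifiers occur in that release in the same version. Coordinates of named genes are GRCh38 positions from the same release.

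Each column was assigned to a cell line and a treatment by its header, and lines served as replicates (MDA-MB-231 as replicate 1, MDA-MB-436 as replicate 2, MDA-MB-453 as replicate 3). The headers name the control columns shControl, while the sample labels state no treatment for them, so whether the controls carried a control hairpin is not settled by the sources used here. To check the pairing by line, correlations across genes (genes are not independent replicates) were computed between libraries after centring each gene. They ranged from 0.358 to 0.953 between libraries of the same line and from -0.914 to 0.09 between libraries of different lines.

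Genes with an RPKM of at least 1 in at least 3 of the 9 libraries were tested (12965 genes). The values were transformed to log2(RPKM + 1) and fitted with limma 3.58.1 (with statmod 1.5.0 in R 4.3.3) with treatment and cell line as terms, so that the treatments are compared within lines, which leaves 4 residual degrees of freedom. Moderation used a mean-variance trend, p-values are two-sided, and they were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Fold changes are those of RPKM + 1, averaged over lines on the log scale, so they are not ratios of the RPKM printed beside them. Errors of log2 fold changes are the limits of 95% confidence intervals of that fit. The contrasts were GSK343 against control, shEZH2 against control, the mean of both against control, and GSK343 against shEZH2. A second limma model, with a mean for each line in the control and in the targeted state (3 residual degrees of freedom), tested whether the response differed between lines by an F-test. An exact sign-flip test on 3 pairs cannot give a two-sided p below 0.25, so limma's p, which borrows the spread of other genes, is the only test used for single genes.

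Gene groups were tested with camera at its preset correlation of 0.01 over 32 lists holding 1100 genes, all of them found in the table. Of these lists 31 had at least 5 tested members and were tested, with adjustment over the lists. An estimated correlation and fry were run beside it. Named genes follow a fixed rule: per contrast, up to 10 genes in each direction with the largest fold change among those past the threshold with the same sign in all 3 lines; where fewer passed, genes with the same sign in all 3 lines and the smallest unadjusted p filled the places and are said not to pass. The rule adds up to 4 members per list with the smallest p, EZH2, EZH1, SUZ12 and EED, 5 genes per direction and line for the counts within lines, and 10 genes for the difference between lines. The groups compared, the tests of genes and lists, the lists, the naming rule and the alternative settings were fixed before the data were examined. The measures that compare the libraries labelled MDA-MB-453 with the other lines were chosen after the values were seen.

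Alternatives tried 1 at a time were pseudocounts of 0.1 and 0.5, no filter on low values, a mean RPKM of at least 5, rescaling by median ratios or to a common sum (TPM scale), moderation without the trend or with robust variances, no replicate block, only the 6 libraries of a comparison, and leaving out each library or each line. In simulated data of the same size, where 100 genes changed 2-fold and 100 changed 1.5-fold, the tests recovered 96%, 99%, 100% and 98% of the 2-fold genes for GSK343, shEZH2, either intervention and the direct comparison. The recovered shares of the 1.5-fold genes were 45%, 31%, 55% and 35%. False calls were 14 of 155, 9 of 139, 14 of 169 and 8 of 141. For the difference between lines 97% of genes with a 4-fold and 28% with a 2.25-fold difference in 1 line were recovered, with 23 false calls among 148. With no change simulated, the 5 tests called between 0 and 1 genes. Camera called the single list that had been shifted and 0 of the others. The simulated genes varied independently of each other, while correlations estimated within the real lists reached 0.858. The simulation therefore does not measure false list calls in the real data.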

Results

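Gene expression was measured by RNA sequencing of total RNA in 3 human cell lines derived from triple-negative breast cancer, MDA-MB-231, MDA-MB-436 and MDA-MB-453. Each line was sequenced as a control, after GSK343 and after shEZH2, which gave 3 libraries per group and 9 libraries in total. GSK343 is a small-molecule inhibitor of EZH2, the catalytic subunit of Polycomb repressive complex 2 (PRC2), which methylates lysine 27 of histone H3. shEZH2 is a short hairpin RNA directed at the EZH2 transcript. The series asks how expression responds when EZH2 is targeted by knockdown or by inhibition. Each line has 1 library per condition, so the lines are the replicates. With the line as a term of the model, p-values measure only how far the treatment differences vary between lines.

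The deposited RPKM correspond to about 16759000, 16785000 and 16112000 reads in the control libraries of MDA-MB-231, MDA-MB-436 and MDA-MB-453. The same calculation gave 14757000, 16565000 and 15342000 reads in the libraries labelled GSK343 and 18283000, 17801000 and 16626000 in those labelled shEZH2. Between 22975 and 27230 genes had a value above 0 in a library, and the 10 most abundant genes held 11.6% to 18.0% of the RPKM total. The first principal component (72.8% of the variance) parted the lines and the second (11.4%) placed the 3 controls at negative scores and the 6 other libraries at positive scores.

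EZH2 transcript (ENSG00000106462.10, chromosome 7, 148807383 to 148884321, minus strand) was lowest in the libraries labelled GSK343, not in those labelled shEZH2. Its RPKM was 27.4, 38.9 and 42.3 in the controls of MDA-MB-231, MDA-MB-436 and MDA-MB-453 (mean 36.2 ± 7.82 SD, n = 3). In the libraries labelled GSK343 it was 5.77, 7.53 and 7.99 (mean 7.1 ± 1.17 SD, n = 3), and in those labelled shEZH2 it was 16.4, 37.4 and 16.2 (mean 23.3 ± 12.2 SD, n = 3). GSK343-labelled libraries had 4.55-fold less EZH2 than controls on the scale of RPKM + 1 (log2 fold change -2.19 ± 0.47, adjusted p = 0.000424, lower in 3 of 3 lines). For the libraries labelled shEZH2 the log2 fold change was -0.70 ± 0.47 and did not pass the threshold (adjusted p = 0.0597), with -0.71, -0.06 and -1.33 in MDA-MB-231, MDA-MB-436 and MDA-MB-453. The direct difference, -1.49 ± 0.47, had an adjusted p of 0.117 and the same sign in 3 of 3 lines. A hairpin acts on the transcript and an enzyme inhibitor on the protein, so EZH2 runs against the labels, and the groups are therefore named below as libraries labelled GSK343 or shEZH2. EZH1, SUZ12 and EED, further PRC2 core genes, did not pass: the log2 fold changes under the GSK343 and shEZH2 labels were 0.41 and 0.33 for EZH1, the paralogous methyltransferase, -0.17 and -0.17 for SUZ12, and -0.08 and -0.16 for EED. EZH2 in the shEZH2-labelled libraries passed without the shEZH2-labelled library of MDA-MB-436 (-1.03) and, at -0.70, without the GSK343-labelled library of that line. The direct difference passed without the shEZH2-labelled library of MDA-MB-453 (-1.79).

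**Figure D1:**
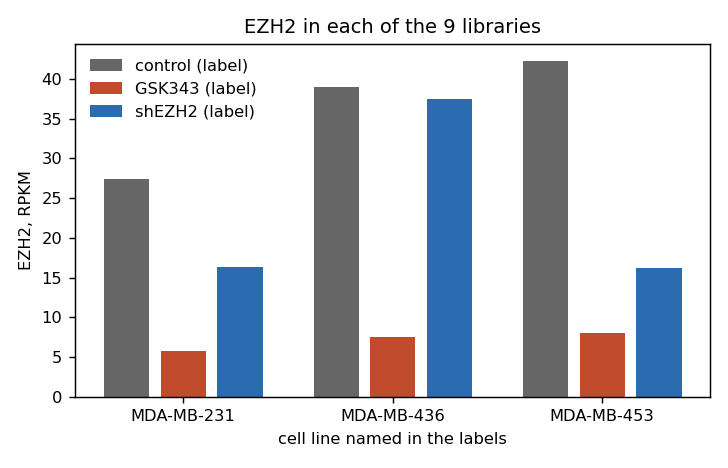
EZH2 RPKM (vertical axis, bars from 0) in each of the 9 libraries, grouped by the cell line named in the labels and coloured by the labelled treatment, 1 library per bar. The libraries labelled GSK343 lie between 5.77 and 7.99, below the 16.2 to 37.4 of the libraries labelled shEZH2 and the 27.4 to 42.3 of the controls.

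The libraries labelled MDA-MB-453 held few genes of their own, as measures chosen after the values were seen showed. Of 30 luminal genes, 1 (SLC39A6, a zinc transporter) was highest in the libraries labelled MDA-MB-453 in all 3 conditions. Genes at 5 RPKM or more in the library labelled MDA-MB-453 and under 0.5 in both other lines numbered 0, 0 and 1 in the 3 conditions, against 139 to 191 when MDA-MB-231 and MDA-MB-436 were compared with each other. Weights of 0.462 for MDA-MB-231 and 0.41 for MDA-MB-436 described the control library best. They were 0.484 and 0.447 for the GSK343-labelled library and 0.511 and 0.477 for the shEZH2-labelled library. Expression lay outside the range of the other lines by a factor of 1.25 for 22.4%, 1.69% and 0.138% of the abundant genes. If these libraries are not a line of their own, the 3 replicates are not independent, so the counts of genes are also given without them. Of 295 calls of genes named by the fixed rule, 239 were lost without them.

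**Figure D2:**
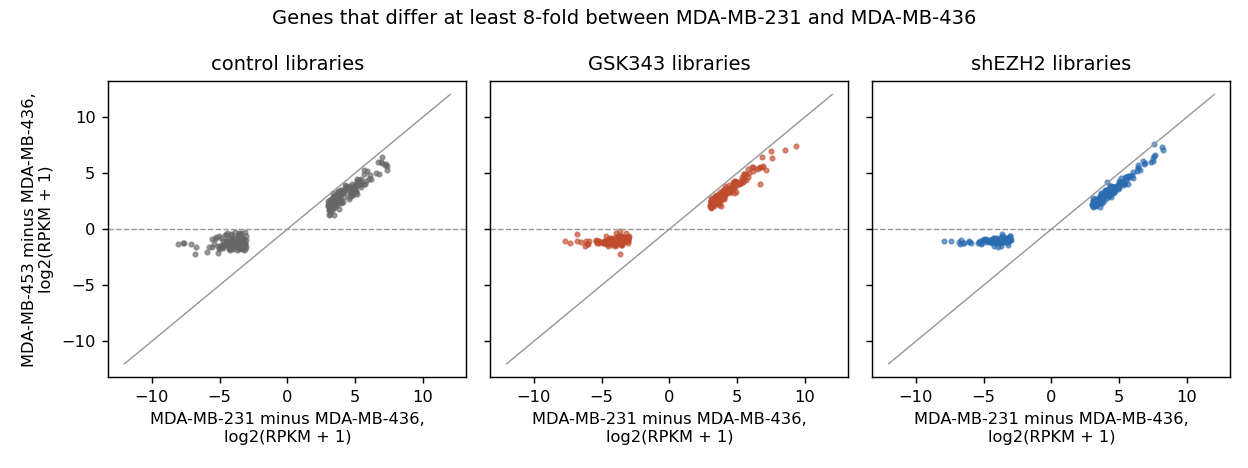
Difference in log2(RPKM + 1) between the libraries labelled MDA-MB-453 and MDA-MB-436 (vertical axis) against the difference between MDA-MB-231 and MDA-MB-436 (horizontal axis), 1 point per gene, for the 241 control, 267 GSK343-labelled and 276 shEZH2-labelled genes that differ at least 8-fold between MDA-MB-231 and MDA-MB-436. The points lie between the line where MDA-MB-453 equals MDA-MB-231 (diagonal) and the line where it equals MDA-MB-436 (dashed), apart from 2 genes of the shEZH2-labelled libraries that lie just beyond the diagonal.

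Libraries labelled GSK343 were compared with the controls to find the response to the inhibitor named in the labels. LCN2 (ENSG00000148346.11, chromosome 9, 128149071 to 128153455), an iron-siderophore binding protein of innate immunity, rose 13.1-fold (log2 fold change 3.72 ± 0.61, adjusted p = 7.61e-05), from a mean RPKM of 17.8 ± 11.8 to 219 ± 30.6 (SD, n = 3). The myeloid growth factors CSF2 and CSF3 rose 8.72-fold and 5.38-fold, the stress cytokine GDF15 7.06-fold, the acute-phase protein SAA1 5.39-fold and the prostaglandin synthase PTGS2 5.37-fold, with adjusted p between 0.000136 and 0.0019 and the same sign in 3 of 3 lines. EZH2, CAV1 (the main caveolae protein, 2.83-fold, adjusted p = 0.000462), LMNB1 (lamin B1, 2.78-fold, adjusted p = 0.0019), ID1 (an inhibitor of helix-loop-helix factors, 2.43-fold, adjusted p = 0.00391) and the pseudogene AC108463.2 (2.31-fold, adjusted p = 0.00158) fell. MMP3, PDZK1IP1 and GPNMB also stood among the 10 largest increases (log2 fold changes 3.30, 3.06 and 2.39). Without the control library labelled MDA-MB-453 none of these 3 passed (2.70, 2.52 and 2.08). MMP3 did not pass either without the control of MDA-MB-231 (2.66) or the GSK343-labelled libraries of MDA-MB-231 (1.92) and MDA-MB-453 (3.67), nor PDZK1IP1 without the GSK343-labelled library of MDA-MB-231 (2.73).

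Among the gene groups, 14 of 29 NF-kB target cytokines and regulators rose under the GSK343 label (20 adjusted over the list alone), among them IL6 (1.95 ± 0.30), CXCL8 (1.93 ± 0.41) and CXCL2 (1.90 ± 0.41). This list was called higher by camera (adjusted p = 3.66e-12, and adjusted p = 0.14 with an estimated correlation). Of 40 autophagy and lysosome genes 14 rose (18 adjusted over the list alone), among them the autophagosome proteins WIPI1 (1.17 ± 0.30) and MAP1LC3A (1.10 ± 0.35), and the list was called higher (adjusted p = 8.37e-07, and adjusted p = 0.17 with an estimated correlation). Replication-dependent histone genes rose in 8 of 15 cases and fell in 1 (9 and 1 adjusted over the list alone), with HIST1H2BK at 1.33 ± 0.45 and HIST2H2BE at 1.29 ± 0.37 (list adjusted p = 0.000418, and adjusted p = 0.553 with an estimated correlation). Of 48 mitosis genes 8 fell and 0 rose (9 fell adjusted over the list alone). The list was called lower (median log2 fold change -0.31, adjusted p = 4.08e-11, and adjusted p = 0.553 with an estimated correlation). Of 12 PRC2 core and accessory genes EZH2 and PHF19 (-0.86 ± 0.29, adjusted p = 0.00389) fell and PHF1 (0.48 ± 0.29, adjusted p = 0.0494) rose (3 lower and 1 higher adjusted over the list alone). PHF1 did not pass with any single one of the 9 libraries left out (0.44 to 0.56). The PRC2 list was called lower (adjusted p = 0.0159, and adjusted p = 0.553 with an estimated correlation), but not without the control library labelled MDA-MB-453 (median -0.01). It holds EZH2 itself and was not tested without that gene, so the call is partly the EZH2 result.

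For the libraries labelled GSK343 1018 of 12965 genes passed, 810 higher and 208 lower, of which 1005 had the same sign in all 3 lines. At unadjusted p under 0.05 there were 3347 genes, against 648 from chance alone. At least 2-fold changes numbered 196 up and 15 down. Without the 3 libraries labelled MDA-MB-453 43 genes passed (37 higher, 6 lower). The count moved by more than 1.5 times without the control (289) or the GSK343-labelled library (317) of MDA-MB-453 and without the GSK343-labelled libraries of MDA-MB-231 (490) and MDA-MB-436 (619). Median-ratio rescaling gave 517 higher and 444 lower, so the excess of increases depends on the scaling. At the preset correlation camera called 12 of 31 lists (6 higher, 6 lower), and 0 with an estimated correlation, while fry called 3. Fry's calls included matrix metalloproteases and invasion genes (fry adjusted p = 0.0276), which camera did not call.

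Libraries labelled shEZH2 were compared with the controls to find the response to the knockdown named in the labels. LCN2 rose 15.2-fold (3.93 ± 0.61, adjusted p = 6.16e-05), to a mean RPKM of 253 ± 32.4 (SD, n = 3) from 17.8 ± 11.8 in the controls. The acute-phase proteins SAA2 and SAA1 rose 7.42-fold and 7.32-fold, CSF2 7.32-fold, GDF15 7.02-fold, the interferon-induced mitochondrial protein IFI6 5.29-fold and the neutrophil chemokine CXCL8 4.91-fold, with adjusted p between 6.16e-05 and 0.0018 and the same sign in 3 of 3 lines. CAV1 fell 2.66-fold (-1.41 ± 0.33, adjusted p = 0.000691), the splicing factor SRSF1 2.14-fold (-1.10 ± 0.34, adjusted p = 0.00238) and LMNB1 2.12-fold (-1.09 ± 0.42, adjusted p = 0.00839). PDZK1IP1 (3.12), GPNMB (2.33) and the complement protein C3 (2.27) also passed. Those 3 and LMNB1 did not pass without the control library labelled MDA-MB-453 (2.58, 2.01, 2.29 and -1.05).

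In the libraries labelled shEZH2 16 of 29 NF-kB targets rose (21 adjusted over the list alone), with IL6 at 1.79 ± 0.30 (list adjusted p = 1.67e-12, and adjusted p = 0.133 with an estimated correlation). Of 40 autophagy and lysosome genes 13 rose (19 adjusted over the list alone), with MAP1LC3A at 1.27 ± 0.35 and WIPI1 at 1.20 ± 0.30 (list adjusted p = 1.79e-06, and adjusted p = 0.177 with an estimated correlation). Of the antigen presentation genes, 7 of 17 MHC class I genes rose (9, and 1 lower, adjusted over the list alone), with HLA-B at 0.99 ± 0.30 and HLA-C at 0.80 ± 0.30 (list adjusted p = 0.00206, and adjusted p = 0.436 with an estimated correlation). Of 9 MHC class II genes 3 rose (9 adjusted over the list alone), among them the protease CTSS (1.45 ± 0.37), with a list adjusted p of 0.000103 (adjusted p = 0.516 with an estimated correlation). Interferon-stimulated genes rose in 11 of 40 cases (15 adjusted over the list alone), among them IFI6 (2.40 ± 0.35), ISG20 (1.23 ± 0.36) and the interferon signal transducer STAT2 (1.20 ± 0.31). That list was called higher (adjusted p = 5.63e-05, and adjusted p = 0.516 with an estimated correlation), but not without the control library of MDA-MB-436 (median 0.16). Of 34 cholesterol synthesis genes and SREBP targets 6 rose (11 adjusted over the list alone; list adjusted p = 0.00149, and adjusted p = 0.516 with an estimated correlation).

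For the libraries labelled shEZH2 1377 genes passed, 1082 higher and 295 lower, of which 1361 had the same sign in all 3 lines. At unadjusted p under 0.05 there were 3705, and at least 2-fold changes numbered 236 up and 12 down. Without the 3 libraries labelled MDA-MB-453 16 genes passed (15 higher, 1 lower). The count moved by more than 1.5 times without the control (322) or the shEZH2-labelled library (449) of MDA-MB-453 and without the shEZH2-labelled libraries of MDA-MB-231 (410) and MDA-MB-436 (910). Median-ratio rescaling gave 796 higher and 620 lower. At the preset correlation camera called 13 of 31 lists (8 higher, 5 lower), and 0 with an estimated correlation, while fry called 6. Fry's calls included apoptosis regulators (fry adjusted p = 0.0143), p53 targets (0.0293) and invasion genes (0.00677), which camera did not call.

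The mean of both interventions against control asks which genes respond to targeting EZH2 by any of the means. LCN2 rose 14.1-fold (3.82 ± 0.53), CSF2 7.99-fold, GDF15 7.04-fold (2.82 ± 0.44), IFI6 4.66-fold (2.22 ± 0.30) and IL6 3.65-fold (1.87 ± 0.26), with adjusted p between 1.14e-05 and 0.000103 and the same sign in 3 of 3 lines. CAV1 fell 2.75-fold (-1.46 ± 0.29, adjusted p = 0.000152), EZH2 2.72-fold (-1.44 ± 0.41, adjusted p = 0.000962), LMNB1 2.43-fold (-1.28 ± 0.37, adjusted p = 0.00102) and NQO1, an NRF2-controlled quinone reductase, 2.29-fold (-1.19 ± 0.48, adjusted p = 0.00532). The cell-cycle inhibitor CDKN1A rose 2.74-fold (1.45 ± 0.30, adjusted p = 0.000183) and the stress transcription factor DDIT3 2.77-fold (1.47 ± 0.39, adjusted p = 0.00069).

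Across both interventions 19 of 29 NF-kB targets rose (21 adjusted over the list alone; list adjusted p = 3.93e-12, and adjusted p = 0.14 with an estimated correlation). Of 40 autophagy and lysosome genes 17 rose (20 adjusted over the list alone), among them WIPI1 (1.18 ± 0.26), the ATG8 family member GABARAPL1 (0.95 ± 0.26) and the lysosomal sialidase NEU1 (1.08 ± 0.30), with a list adjusted p of 8.34e-07 (adjusted p = 0.17 with an estimated correlation). Of 22 immediate-early genes 14 rose (14, and 1 lower, adjusted over the list alone), among them DUSP1 (1.07 ± 0.29), FOSB (0.79 ± 0.27), NR4A1 (0.79 ± 0.30) and ZFP36 (0.80 ± 0.34; list adjusted p = 9.33e-05, and adjusted p = 0.537 with an estimated correlation). Of 15 replication-dependent histone genes 9 rose and 1 fell (10 and 1 adjusted over the list alone; list adjusted p = 0.000387, and adjusted p = 0.537 with an estimated correlation). The 9 included HIST1H2BD (1.34 ± 0.34), HIST1H2BK (1.32 ± 0.39) and HIST2H2BE (1.24 ± 0.32).

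Lists of immune recognition genes were called higher. Of 40 interferon-stimulated genes 13 rose (13 adjusted over the list alone; list adjusted p = 0.000387, and adjusted p = 0.537 with an estimated correlation), a list call lost without the control library of MDA-MB-436 (median 0.07). Of 17 MHC class I genes 7 rose (9, and 1 lower, adjusted over the list alone), among them HLA-B (0.84 ± 0.26), HLA-C (0.64 ± 0.26) and the light chain B2M (0.56 ± 0.25), with a list adjusted p of 0.0124 (adjusted p = 0.537 with an estimated correlation). Of 9 MHC class II genes 3 rose, CTSS most (1.47 ± 0.32; 9 adjusted over the list alone; list adjusted p = 0.000494, and adjusted p = 0.537 with an estimated correlation). Of 34 cholesterol genes 9 rose (9 adjusted over the list alone), among them MVD of the mevalonate pathway (0.97 ± 0.40), with a list adjusted p of 0.00713 (adjusted p = 0.537 with an estimated correlation).

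Lists of growth genes were called lower by camera. Fry did not call any list of this paragraph (fry adjusted p = 0.0659 for DNA replication, 0.16 for mitosis and 0.309 for oxidative phosphorylation). Of 41 DNA replication genes 11 fell (12 adjusted over the list alone), among them GINS2 of the replicative helicase (-0.76 ± 0.29), the sliding clamp PCNA (-0.61 ± 0.27) and TYMS, which makes thymidylate (-0.55 ± 0.26), with a list adjusted p of 2.42e-05 (adjusted p = 0.537 with an estimated correlation). Of 48 mitosis genes 9 fell (9 adjusted over the list alone, list adjusted p = 5.78e-07, and adjusted p = 0.537 with an estimated correlation). The mitotic kinase PLK1 (-0.63 ± 0.31) was among them and did not pass without the control library of MDA-MB-436 (-0.51). The median of the mitosis list was -0.000752 in MDA-MB-231, -0.245 in MDA-MB-436 and -0.432 in MDA-MB-453. In MDA-MB-231 it was -0.14 under the GSK343 label and 0.158 under the shEZH2 label. Oxidative phosphorylation genes (46 tested) were called lower as a list with 0 members past the threshold over all genes or adjusted over the list alone (median -0.20, list adjusted p = 5.86e-05, and adjusted p = 0.573 with an estimated correlation). Of 55 cytoplasmic ribosomal proteins 1 rose and 1 fell (0 adjusted over the list alone), with a median of -0.16 and a list adjusted p of 0.000385 (adjusted p = 0.637 with an estimated correlation). Both of these list calls were lost without the control library of MDA-MB-436 (medians -0.06 and -0.04). Of 38 homologous recombination and DNA damage repair genes 3 fell (1 adjusted over the list alone; list adjusted p = 0.0166, and adjusted p = 0.616 with an estimated correlation), a call lost without the control (median 0.06) or the shEZH2-labelled library (median -0.04) of MDA-MB-453. The break sensor NBN (-0.78 ± 0.36) fell most of the 3 and did not pass without the control library of MDA-MB-453 (-0.53). Of 12 PRC2 genes EZH2 and PHF19 (-0.80 ± 0.25) fell and PHF1 (0.57 ± 0.26) rose (5 lower and 2 higher adjusted over the list alone). The PRC2 list was called lower (adjusted p = 0.0263, and adjusted p = 0.537 with an estimated correlation), but not without the control library labelled MDA-MB-453 (median -0.02). As above, the list holds EZH2 and was not tested without it.

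Apart from the PRC2 list, camera did not call the lists most tied to Polycomb repression and to cell identity. Fry, which asks whether the genes of a list move to 1 side without comparing them with other genes, called tumour suppressors (adjusted p = 0.05 as rounded) and matrix metalloproteases and invasion genes (adjusted p = 0.00742) higher. The list p-values that follow are camera's. Of 57 tested developmental regulators under Polycomb 0 rose and 1 fell (0 and 1 adjusted over the list alone; list adjusted p = 0.732). That gene, the nuclear receptor NR2F2 (-0.51 ± 0.25), did not pass without the control library of MDA-MB-231 (-0.45). Of 39 HOX genes 19 were tested and 2 rose (1 adjusted over the list alone, list adjusted p = 0.184), with HOXB9 at 0.92 ± 0.27. PRC1 subunits gave 0 of 20 (0 adjusted over the list alone; list adjusted p = 0.358). Of 28 tumour suppressors described as silenced by EZH2 6 rose, among them CDKN1A and the ubiquitin ligase component FBXO32 (0.75 ± 0.31), and 2 fell, among them the guidance ligand SLIT2 (-0.85 ± 0.28; 9 and 3 adjusted over the list alone; list adjusted p = 0.681). Of 30 mesenchymal genes 5 rose, among them fibronectin FN1 (0.69 ± 0.28) and the collagen crosslinker LOX (0.99 ± 0.27), and 3 fell, among them CAV1 and the receptor kinase AXL (-0.71 ± 0.29; 5 and 3 adjusted over the list alone; list adjusted p = 0.816). Of 27 matrix metalloproteases and invasion genes 11 rose, among them the chemokine receptor CXCR4 (0.93 ± 0.31), and 4 fell (13 and 4 adjusted over the list alone; list adjusted p = 0.159). Epithelial genes gave 6 higher and 1 lower of 18 (6 and 3 adjusted over the list alone; list adjusted p = 0.409). Basal mammary genes gave 2 higher and 3 lower of 14 (5 and 5 adjusted over the list alone; list adjusted p = 0.358), with a median of -0.01 and a mean of 0.01, and CAV2, a caveolin, was among the lower (-0.69 ± 0.26). In the luminal list 2 were higher and 2 lower of 19 (4 and 3 adjusted over the list alone; list adjusted p = 0.816). Stem-like breast cancer markers gave 1 higher, CD24 (0.92 ± 0.30), and 2 lower of 17, among them SOX9 (-0.61 ± 0.27; 2 and 4 adjusted over the list alone; list adjusted p = 0.409).

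Camera did not call the stress and survival lists either, while fry called apoptosis regulators (adjusted p = 0.0179) and p53 targets (adjusted p = 0.0224) higher. Apoptosis regulators gave 6 higher of 35 (8 adjusted over the list alone; list adjusted p = 0.182), among them the BH3-only protein BMF (0.73 ± 0.29). p53 targets gave 5 higher and 1 lower of 26 (8 and 2 adjusted over the list alone; list adjusted p = 0.184), among them CDKN1A, GDF15 and SESN2 (0.95 ± 0.35). Unfolded protein response and ATF4 targets gave 8 higher and 1 lower of 35 (9 and 3 adjusted over the list alone; list adjusted p = 0.816). Hypoxia and glycolysis genes gave 6 higher, among them the enolase ENO2 (1.12 ± 0.28), and 1 lower of 29 (8 and 2 adjusted over the list alone; list adjusted p = 0.962), the lactate dehydrogenase LDHA (-0.67 ± 0.27). NRF2 antioxidant genes gave 4 higher, among them ferritin FTH1 (1.17 ± 0.45), and 1 lower of 22, NQO1 (4 and 4 adjusted over the list alone; list adjusted p = 0.203). Mitochondrially encoded genes gave 1 higher of 15 (1 adjusted over the list alone; list adjusted p = 0.968). Markers of fibroblasts and endothelium gave 2 higher of 8 (2 adjusted over the list alone; list adjusted p = 0.358), and of the 16 immune cell markers 2 passed the filter on low values, too few to test.

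For the mean of both interventions 2141 genes passed, 1584 higher and 557 lower, of which 2094 had the same sign in all 3 lines. At unadjusted p under 0.05 there were 4267, and at least 2-fold changes numbered 208 up and 10 down. Without the 3 libraries labelled MDA-MB-453 145 genes passed (128 higher, 17 lower). Without the control library of that name 673 passed, and without its GSK343-labelled library 1294. Median-ratio rescaling gave 1129 higher and 1151 lower, so no excess of increases remained. At the preset correlation camera called 14 of 31 lists (8 higher, 6 lower), and 0 with an estimated correlation, while fry called 8. LCN2, IL6, GDF15, CXCL8 and IFI6 passed with each single library and each line left out.

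**Figure D3:**
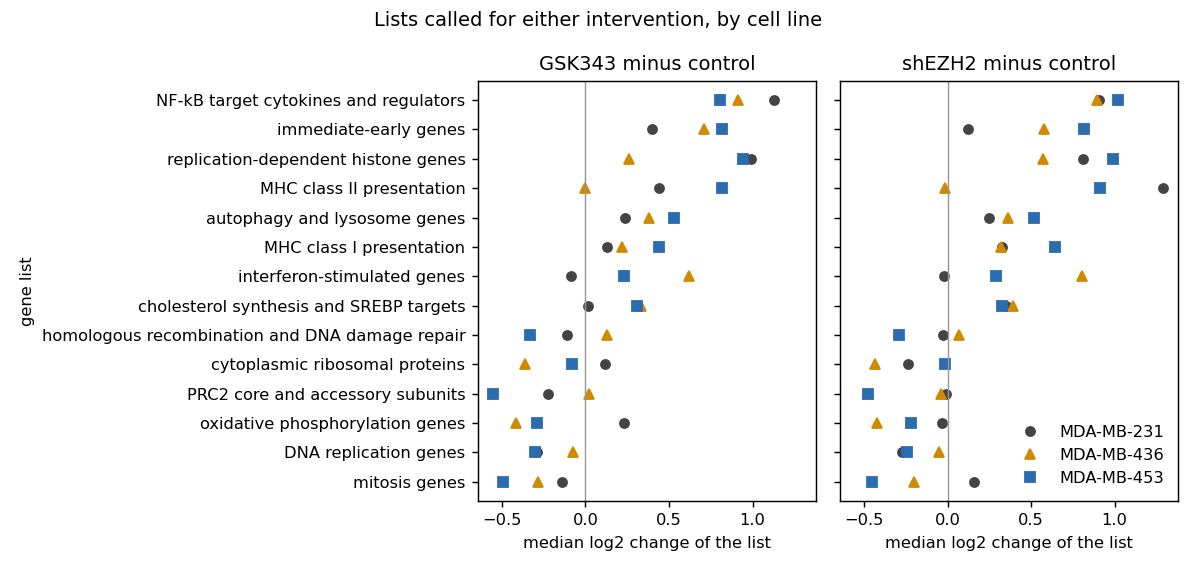
Median log2 change of the 14 lists called for either intervention (horizontal axis), in libraries labelled GSK343 and shEZH2 against the control of the same line, with 1 symbol per cell line named in the labels. NF-kB targets lie above 0 in all 3 lines, while the lines part on several other lists.

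The direct comparison of the libraries labelled GSK343 with those labelled shEZH2 asks whether the interventions differ in effect. limma called 0 of 12965 genes, and 295 had an unadjusted p under 0.05, fewer than the 648 from chance alone. Genes named for the smallest unadjusted p did not pass, among them EZH2 (-1.49 ± 0.47, adjusted p = 0.117), the U1 small nuclear RNA pseudogene RNU1-106P (1.12 ± 0.34, adjusted p = 0.117) and ID1 (-0.75 ± 0.43, adjusted p = 1). RPPH1, the RNA of ribonuclease P, had an RPKM of 45.4, 34.8 and 27.6 in the libraries labelled GSK343 and of 0.0857, 0 and 22.0 in those labelled shEZH2 (adjusted p = 0.962). A count of 0 does not show equal effects: the confidence interval of the difference extended by a median of 0.34 log2 units to each side, and by 0.44 or less for 90% of genes. The count was 1 without the control of MDA-MB-436, 1 without the shEZH2-labelled library of MDA-MB-436, 2 without the GSK343-labelled library of MDA-MB-453 and 3 without the shEZH2-labelled library of MDA-MB-453.

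Fold changes of the libraries labelled GSK343 and shEZH2 against the same controls were compared across genes, as a measure of how alike the responses were. Pearson's r across the 12965 genes was 0.676 in MDA-MB-231, 0.892 in MDA-MB-436, 0.924 in MDA-MB-453 and 0.901 for the mean over lines. Unchanged groups simulated against shared controls gave about 0.50. The covariance for the mean was 0.121, against 0.0144 simulated. Genes are not independent replicates and the controls of a line are shared, so no p is given and the error of the control libraries counts toward both fold changes. Of the genes called for both labels, 654 were higher in both and 137 lower in both, and 0 had opposite signs. Without the 3 libraries labelled MDA-MB-453, 43 genes passed under the GSK343 label and 16 under the shEZH2 label, so at most 16 could be shared. Pearson's r for the mean over lines was then 0.814. Unchanged groups simulated against shared controls gave a mean of 0.15 shared calls (largest 1, 20 simulations). The simulated groups held no offset common to the control libraries, which alone would raise r, the covariance and the shared calls. The simulated values therefore cannot tell alike responses to the interventions from controls that differ from all other libraries. LCN2, CSF2, GDF15 and SAA1 stand in the shared increases and CAV1 and LMNB1 in the shared decreases.

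**Figure D4:**
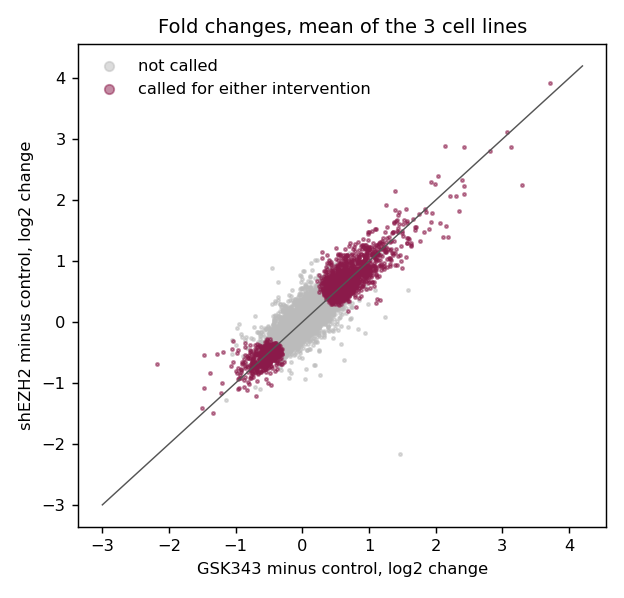
Log2 fold change against control of the libraries labelled shEZH2 (vertical axis) against those labelled GSK343 (horizontal axis), mean of the 3 lines, 1 point per gene for the 12965 tested genes, with the genes called for either intervention in colour. The points follow the diagonal of equal change (r = 0.901 across genes), and EZH2 lies off it at -2.19 and -0.70.

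Responses of the lines were compared to ask which genes react to EZH2 targeting in some lines only. PDZK1IP1, a membrane protein of epithelial cells, had log2 changes of 4.33 in MDA-MB-231, 0.77 in MDA-MB-436 and 4.18 in MDA-MB-453 (adjusted p = 0.00361). HSD17B14, a steroid dehydrogenase, had 0.25, 3.04 and 2.26 in the same order (adjusted p = 0.0242), and VGF, a secreted neuropeptide precursor, -0.53, 1.98 and 1.98 (adjusted p = 0.0408). These 3 genes passed of 12965, and 3710 had an unadjusted p under 0.05. H1F0, a linker histone (-0.96, 1.17 and 0.11), and the cytokine IL1B (3.47, 0.91 and 1.12) came next and did not pass (adjusted p = 0.0676). The spread in this test is the difference between the GSK343-labelled and shEZH2-labelled libraries of a line, so a differing control library cannot be told from a differing response. The libraries labelled MDA-MB-453 may be a mix of the other lines. Their values need not be a separate response, and the F-test then does not compare 3 independent lines. The count was 3966 without the GSK343-labelled and 4049 without the shEZH2-labelled library of MDA-MB-231, and 0 without the GSK343-labelled or shEZH2-labelled library of MDA-MB-436 or MDA-MB-453.

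Within each line, genes moved at least 2-fold in the same direction under both labels were counted, with no test since each value rests on 1 library. There were 164 higher and 32 lower among 11850 genes in MDA-MB-231, 225 and 16 among 12155 in MDA-MB-436, and 445 and 65 among 12774 in MDA-MB-453. Opposite 2-fold changes numbered 2, 1 and 0. Ranked by the smaller of the changes under both labels, the first in MDA-MB-231 were PDZK1IP1, LCN2, IL1B, the chemokine CXCL1 and C3 upward and included NQO1 downward. In MDA-MB-436 the first by that rank were GPNMB, the immediate-early factor EGR1, HSD17B14, PTGS2 and PNLIPRP3 upward and included COL13A1 and THBS1 (thrombospondin) downward. In the libraries labelled MDA-MB-453 they were PDZK1IP1, LCN2, CSF2, MMP3 and SAA1 upward and included CAV1 and the glypican GPC6 downward.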

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

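The tests of a mix, of pooled control RNA, of the MDA-MB-453 label, of exchanged labels and of slower cycling were chosen only after the results were seen, and the other tests before.

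On the first principal component the libraries labelled MDA-MB-453 lay between those of MDA-MB-231 and MDA-MB-436 in all 3 conditions. The tables argue against MDA-MB-453 cells as labelled, since 1 of 30 luminal genes, SLC39A6, was highest there in all 3 conditions, against at least 10 set for a line of that type. They argue against columns computed from the other lines too, which would have no genes of their own above 0, since at least 1649 such genes were found in each condition. A mix of MDA-MB-231 and MDA-MB-436 RNA or cells may account for the pattern: over the 3 conditions 1 gene was at 5 RPKM or more in the library labelled MDA-MB-453 and under 0.5 in both others, where fewer than 10 were set for a mix. Pooled RNA of the sequenced controls is argued against, since 22.4% of abundant genes of the control library lay outside the range of the others (1.69% and 0.138% under the GSK343 and shEZH2 labels), while EZH2 was 42.3, 7.99 and 16.2 RPKM against 28.6, 6.16 and 26.2 from such pools; mixed cells or RNA of other cultures stay open, and no further biological explanation was tested.

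EZH2 transcript was lower in the libraries labelled GSK343 than in those labelled shEZH2. The tables argue against slower cell cycling as the whole cause: the lowest direct change among the 89 other DNA replication and mitosis genes was -0.519 (NEK2, SD of the genes 0.133), against -1.49 for EZH2. A part is not excluded, since 46 of 48 mitosis genes had a direct change below 0 (median -0.17). Camera called that list lower (adjusted p = 3.27e-11, and adjusted p = 0.428 with an estimated correlation). Of 41 DNA replication genes 18 lay below 0 and 23 above. Labels of the interventions exchanged could give the pattern. That EZH2 was lower under the GSK343 label in 3 of 3 lines is the pattern itself, so it is no separate evidence for an exchange. Under an exchange, the inhibitor-treated libraries would also hold less EZH2 than the controls in MDA-MB-231 and MDA-MB-453. The cholesterol list, set as a sign of an inhibitor response, was lower under the GSK343 label (camera p = 0.00226, and p = 0.211 with an estimated correlation), with medians of -0.30, 0.00 and 0.06 in MDA-MB-231, MDA-MB-436 and MDA-MB-453, so it decides nothing about an exchange. Exchanged labels and a weak knockdown beside an inhibitor that lowers the transcript cannot be told apart, because no measure of EZH2 protein, histone methylation or the hairpin is given in the sources used here.

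The 3 control libraries stood apart from the 6 others. The tables argue against trends with GC content and gene length as the whole cause, since 82.9% of the genes called for either intervention (1774 of 2141) were called in the same direction after both trends were removed (1511 higher and 1861 lower genes then passed, a balance that rescaling by median ratios alone also gives, with 1129 and 1151). A library or read-processing batch, which the labels do not name, cannot be told apart from the interventions, since it would part the same libraries. The test made covered only a batch that raises processed pseudogenes, and the values argue against that kind. The median change of processed pseudogenes minus that of protein-coding genes lay between -0.164 and 0.0436 in the 6 differences from control, below the bound set. Genes above 0 numbered 22975, 23604 and 23900 in the controls and 24430 to 27230 in the 6 others. Medians of long intergenic and antisense RNAs were up to 0.28 and 0.29, above the 0.01 to 0.10 of protein-coding genes in 5 of the 6 differences, but 0 and 0.01 in the shEZH2-labelled library of MDA-MB-231, where LCN2 rose by 4.67. Release of Polycomb target genes, the explanation that the design names, was neither shown nor excluded for the developmental regulators (adjusted p = 0.732 by camera, and 0.614 before adjustment over the lists), and handling of the cells shared by both interventions was not tested, so both stay open.

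Genes stood out where the test of the difference between lines passed. PDZK1IP1 changed by 4.33, 0.77 and 4.18 log2 units in MDA-MB-231, MDA-MB-436 and MDA-MB-453 (adjusted p = 0.00361). HSD17B14 changed by 0.25, 3.04 and 2.26 in that order (adjusted p = 0.0242). VGF changed by -0.53, 1.98 and 1.98 in that order (adjusted p = 0.0408). If the libraries labelled MDA-MB-453 are a mix of the other lines, the third value of each gene is not a separate response.

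Other splits of the samples were fitted for each count. For either intervention, 81 of the 84 splits of 9 libraries into 3 and 6 could be fitted in a model of 2 groups with the line as a block. The real split gave 2461 genes and the highest other 39, and 1 of 81 gave as many, so chance can be excluded for the gene count only if the 3 lines are independent. The libraries labelled MDA-MB-453 may be a mix of the other lines (1 of 30 luminal genes highest there), and without them 145 genes passed. Among the 27 splits that part all lines alike, the highest other gave 0. For the lists moved by either intervention 6 of 81 splits gave as many as the real 13, with 15 as the highest other, so chance cannot be excluded. For the difference between lines 3 of 27 splits gave at least the real 3 genes. The others that did (8 and 703 genes) exchanged only the control of MDA-MB-231 and kept those of MDA-MB-436 and MDA-MB-453. They set the labelled comparison in these lines against a false one in MDA-MB-231, so they are no measure of chance. All the rest gave 0. The splits therefore decide nothing about chance, which is not excluded for these genes. The comparisons of 3 libraries with 3 have 10 splits, too few for a share under 0.05. There the real and the highest other counts of genes were 1018 and 0 for GSK343 (1 of 10 as large), 1377 and 0 for shEZH2 (1 of 10) and 0 and 0 for the direct comparison (10 of 10). For lists they were 12 and 11 for GSK343 (1 of 10) and 13 and 13 for shEZH2 (3 of 10).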

How the results depend on the processing

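No test in this part was chosen after the result was seen; all alternatives had been planned. Of 295 gene calls named by the fixed rule, 0 reversed, 130 were kept with each single library left out and 4 were kept under every alternative run. Without replicate 3, the libraries labelled MDA-MB-453, 239 of the 295 lost their call and 56 kept it. Without replicate 1 and without replicate 2, 125 and 44 lost theirs. Of 39 list calls 23 were kept with each single library left out, 0 under every alternative, and 1 reversed. The cause of the shifts was not tested unless stated. With 3 lines and 14757000 to 18283000 reads per library, changes of about 1.5-fold are often missed.

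Without a filter on low values 14 genes passed for GSK343, 15 for shEZH2, 186 for either intervention and 887 for the difference between lines. With no replicate block 2, 2 and 3 genes passed, since the spread between the lines then enters the error. EZH2 under the GSK343 label stayed at -2.187 in both settings but did not pass (adjusted p = 0.0651 without the filter and 0.186 without the block, over a range of 4.51e-24 to 0.186 across its alternatives). A mean RPKM of at least 5 gave 1386 genes for either intervention, 1 for the direct comparison and 7 for the difference between lines. There EZH2 passed under the shEZH2 label at -0.6974 and in the direct comparison at -1.49. Under the shEZH2 label it also passed at -0.7967 after median-ratio rescaling and at -0.6974 with only the 6 libraries of the comparison. On the TPM scale 521 genes passed for GSK343 and 1 for the difference between lines. The values there are larger, so the fixed filter lets more genes through and the pseudocount weighs less, beside the change of scale. With an estimated correlation 0, 0 and 0 lists were called for GSK343, shEZH2 and either intervention, and fry called 3, 6 and 8. Within MDA-MB-231, MDA-MB-436 and MDA-MB-453, 824, 1314 and 2493 genes moved at least 1.5-fold, and 441, 629 and 1146 moved at least 2-fold with a pseudocount of 0.1, the first by a lower limit and the second by more weight on low values. An RPKM of at least 5 left 158 in MDA-MB-436.

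With 1 library or 1 line left out the counts ranged from 43 to 1250 for GSK343, from 16 to 1621 for shEZH2, from 145 to 2053 for either intervention, from 0 to 3 for the direct comparison and from 0 to 4049 for the difference between lines, where a lone library of a group is assumed to vary like the others. The lowest counts for the first 3 came without replicate 3, the libraries labelled MDA-MB-453. EZH2 ranged from -2.338 to -2.007 under the GSK343 label, from -1.028 to -0.3814 under the shEZH2 label and from -1.786 to -1.149 in the direct comparison. The difference between lines could not be estimated without a control library. Among calls, camera's direction reversed for the ribosomal protein list. That list under GSK343 had medians from -0.2174 to 0.01901 (without replicate 2). The repair list kept camera's direction, but its median was above 0 without the control library labelled MDA-MB-453 for GSK343, shEZH2 and either intervention (0.06, 0.04 and 0.06). Among values that had not passed, EED under GSK343 ranged from -0.2351 to 0.1154, SUZ12 under GSK343 from -0.392 to 0.04593 and SUZ12 under shEZH2 from -0.3754 to 0.04379, each above 0 without the control library labelled MDA-MB-453 (0.05, 0.05 and 0.04), and EED also without the GSK343-labelled library of that name (0.08).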

Other observations

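No test in this part was chosen after its result was seen; values without a test are given as described.

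The lists were also tested directly between the libraries labelled GSK343 and those labelled shEZH2. At camera's preset correlation 14 of 31 lists were called, 4 higher and 10 lower under the GSK343 label, while with an estimated correlation 0 were called (lowest adjusted p = 0.428 with an estimated correlation) and fry called 0. Mitosis genes had a median difference of -0.17 (adjusted p = 3.27e-11, and adjusted p = 0.428 with an estimated correlation), with -0.30, -0.11 and -0.12 in MDA-MB-231, MDA-MB-436 and MDA-MB-453. Mitochondrially encoded genes had a median difference of 0.39 (adjusted p = 6.71e-09, and adjusted p = 0.428 with an estimated correlation), with 0.57, 0.02 and 0.61 in the same order. Of the 48 mitosis and 15 mitochondrially encoded genes 0 passed singly over all genes.

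Some lists differed in median between the lines, a difference that was not tested at the level of lists. Against control, interferon-stimulated genes had a median change for either intervention of -0.06 in MDA-MB-231, 0.71 in MDA-MB-436 and 0.27 in MDA-MB-453. MHC class II genes had 0.83, 0 and 0.86 in that order, and mitochondrially encoded genes 0.42, -0.56 and 0.28. Long intergenic non-coding RNAs (377 tested) had medians between 0 and 0.28 and antisense RNAs (401 tested) between 0.01 and 0.29 over the 6 differences from control, against 0.01 to 0.10 for 11330 protein-coding genes. The strand setting of the counting is not given in the sources used here, so reads of overlapping genes may be included in the antisense values; the processed pseudogenes, which could share reads with their parent genes, had medians that differed from those of protein-coding genes by -0.164 to 0.0436.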
